A study of Mus musculus with 111 samples.

How the data were processed

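Gene expression was measured on Affymetrix oligonucleotide arrays of the mouse genome in RNA from sorted striatal cells. Per the labels' protocols, the subventricular zone was removed, the striata of the mice of a litter were pooled by genotype, the tissue was dissociated with papain, myelin and debris were removed on Percoll gradients, and cells were sorted on GLT1 and CD11b. The samples fell into 24 groups by fraction, genotype and age, with 4 to 6 samples per group. Replicate numbers run from 1 to 37, and each number occurs once in each of the 3 fractions. No scan date or batch was given in the sources used here.

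The deposited values are log2 expression values of 45101 probe sets, made by the authors with affy and RMA (background correction, quantile normalization and summary of the probes of a set), and limma is also named, per the submitters' processing notes. The versions, the order of these steps and which arrays were normalized together are not given in the sources used here. The values ranged from 1.50 to 14.26. The sorted values of all arrays were nearly equal (the largest SD of a quantile across arrays was 0.102, and array medians ran from 6.261 to 6.651), which was checked on the values, and no 2 arrays were identical. The values were used as deposited, with no further normalization in the reported fits.

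Probe sets were named from the platform annotation, in which 34958 had 1 gene symbol, 932 several and 9211 none. Only probe sets with 1 symbol named a gene. Symbols were checked through gene identifiers against a reference annotation of the assembly GRCm38.p6, which matched 34754 probe sets and changed 0 symbols. Of several probe sets of a gene, the one with the highest mean over all arrays stood for it, which left 18194 genes. A gene was tested in a fit when its mean over the arrays of that fit reached the 40th percentile of all probe set means there.

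Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). For each fraction and model, the 4 groups (mutant and WT at 2 ages) entered 1 fit of group means, with contrasts of mutant minus WT at each age and of the difference between these effects. P-values were adjusted by Benjamini-Hochberg over all genes tested in a contrast, and a gene was called at an adjusted p below 0.05. WT fractions were compared in 1 fit of all WT samples with age group as an additive term. The difference between the R6/2 effect at 12 weeks and the zQ175 effect at 12 months came from a fit of the 8 groups of a fraction, added after seeing the data. The effects of both models were also correlated across the genes called in R6/2 at 12 weeks. The p for that correlation is exact and one-sided, from all 70 relabellings of the zQ175 and WT samples at 12 months, adjusted over 3 fractions. Overlaps of called genes are given beside the number that independent lists would share. The 2 ages of a model share 1 estimate of the spread of each gene, which favours overlap between ages, so that number is no chance level there.

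Shifts of 24 gene lists, written before the data were examined, were tested with limma's fry, which asks whether the genes of a list move, on balance, 1 way, and whose mixed test asks whether they change in either direction. Neither compares a list with other genes. Adjustment was over the lists within a contrast. Beside each list stand the number of members called over all genes tested and the number adjusted over the list alone. Each list that fry called was also tested with camera and an estimated correlation between genes. Camera asks another question, whether a list shifts more than the other genes tested, so it does not repeat the test of fry. Adjusted p-values given with an estimated correlation come from camera. Lists with fewer than 2 tested members in a fit were left out there. The lists were astrocyte markers, homeostatic microglia markers, disease-associated microglia genes, reactive astrocyte genes, cholesterol biosynthesis, lipid transport and fatty acid metabolism, glutamate and potassium homeostasis, medium spiny neuron genes, pan-neuronal markers, oligodendrocyte markers, oligodendrocyte precursor markers, endothelial and mural markers, border macrophage and blood cell markers, ependymal and subventricular zone markers, proliferation genes, immediate early genes, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, complement genes, heat shock and unfolded protein response, oxidative phosphorylation, glycolysis, homeobox developmental regulators and sex-linked genes. Some genes are on more than 1 list, so the shifts of such lists are not independent. Apoe and Lpl are on the disease-associated and the lipid list. Slc1a2, Slc1a3, Glul, Kcnj10, Gja1, Gjb6, Aqp4 and Atp1b2 are on the astrocyte and the glutamate and potassium list. In all 39 list members were named by no probe set and were not analysed here.

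Genes named in the report followed a rule written before the data were examined. It names, per contrast, the 8 called genes with the largest rise and the 8 with the largest fall, and up to 4 called members of each list by smallest p. Where fewer than 3 genes were called, it names the 5 with the smallest p. Sex-linked genes were kept out of the rankings, and Htt was reported in every genotype contrast. The report gives a selection of the genes the rule names.

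The alternatives were no filter on dim genes, a filter at the 60th percentile, the mean of all probe sets of a gene, quantile normalization within the fit, a fit of only the 2 groups compared, the mean of Y-linked genes as a covariate, limma's arrayWeights, and leaving out each sample in turn. The correlations were also computed over all genes tested in both models, and the WT fractions with the replicate number as a block. The Y-linked mean was planned over Ddx3y, Eif2s3y, Kdm5d and Uty, and Ddx3y was named by no probe set, so 3 genes were used. Alternatives chosen after seeing the data left out the 2 WT samples that lack Y-linked expression, or added the mean of astrocyte markers, of endothelial and mural markers, or of oligodendrocyte, endothelial and mural markers as a covariate in 1 contrast each. Each count of called genes was compared with the counts from other splits of the same samples into groups of equal sizes, at most 100 per count.

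The fits were tested on simulated data with 200 genes changed by a log2 fold change of 0.5, 1 or 2 (those above the dim filter counted). In the simulation of the R6/2 comparison of astrocytes at 12 weeks, on 12209 genes, 64.18%, 90.77% and 100% of the changed genes were called at these sizes, with 6 unchanged genes called. In that of the zQ175 comparison of the negative fraction at 12 months, on 12605 genes, the shares were 14.93%, 59.09% and 95.24%, with 11 unchanged genes called. A list shifted by 0.5 was called in each of the 21 genotype, age and model contrasts simulated. Of the lists not shifted, 1 was called in zQ175 astrocytes at 6 months and 1 in the zQ175 negative fraction at 12 months. The noise was drawn for each gene independently, so the correlation of genes within a list was not simulated. The number of arrays limits the precision of each estimate.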

Results

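The data describe gene expression in cells sorted from the striatum of 2 mouse models of Huntington's disease and of their wild-type (WT) controls. R6/2 mice carry a transgene with the first exon of human huntingtin and were sampled at 6 and 12 weeks of age. zQ175 mice carry an expanded repeat in their own Htt gene and were sampled at 6 and 12 months. Cells were sorted into 3 fractions: astrocytes (GLT1-positive, CD11b-negative), microglia (GLT1-negative, CD11b-positive) and a negative fraction that carried neither surface marker. In each fraction there were 5 R6/2 and 5 WT samples at 6 weeks, 6 R6/2 and 5 WT samples at 12 weeks, and 4 zQ175 and 4 WT samples at each of 6 and 12 months, which makes 24 groups. Striata were pooled by litter and genotype, per the labels, which name no separate animals, so the p-values measure the spread between pooled samples. Group levels are means of log2 array signal ± SD over the samples of a group, and log2 fold changes (mutant minus WT) carry ± their standard error. A gene was called when its adjusted p from limma was below 0.05. Pearson correlations between samples of 1 group ranged from 0.950 in the negative fraction of R6/2 mice at 12 weeks to 0.995.

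In the 18 WT samples of each fraction, the sort separated the marker genes of astrocytes and microglia. Astrocyte markers averaged 12.39 ± 0.06 in the astrocyte fraction, 7.84 ± 0.63 in microglia and 9.08 ± 0.69 in the negative fraction. Homeostatic microglia markers averaged 12.52 ± 0.11 in microglia against 6.19 ± 0.29 in astrocytes. Slc1a2, which encodes the sorted surface protein GLT1, was 4.22 ± 0.18 log2 units higher in astrocytes than in microglia and 3.21 ± 0.18 higher than in the negative fraction. Tmem119, a microglial membrane protein gene, was lower in astrocytes than in microglia by a log2 fold change of -8.49 ± 0.16, and the chemokine gene Ccl12 had the largest such difference, -9.24 ± 0.22. The astrocyte fraction also held oligodendrocyte markers at 12.24 ± 0.18, beside 11.94 ± 0.52 in the negative fraction and 8.97 ± 1.41 in microglia. By limma, 14 of the 14 oligodendrocyte markers were called higher in astrocytes than in microglia and 1 higher in astrocytes than in the negative fraction, and against the latter the list as a whole did not shift (fry adjusted p = 0.272). The negative fraction held the endothelial and mural markers at 12.00 ± 0.34, and Dcx, a gene of migrating young neurons, was higher there than in astrocytes, with a log2 fold change of -6.25 ± 0.27 for astrocytes minus negative. Medium spiny neuron genes averaged 7.09 in astrocytes, 6.27 in microglia and 7.20 in the negative fraction.

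By list, 21 of 21 astrocyte markers were called higher in astrocytes than in either other fraction, with median log2 differences of 5.04 against microglia and 3.47 against the negative fraction. All 16 tested homeostatic microglia markers were called lower in astrocytes than in microglia (median -7.67). All 18 endothelial and mural markers were called lower in astrocytes than in the negative fraction (median -3.14, adjusted p = 0.129 with an estimated correlation). The counts adjusted over the list alone were equal to these. Set against the other genes, by camera with an estimated correlation, the astrocyte list had adjusted p = 0.131 and 0.129 in these comparisons. The microglia list had 0.103 there, and 0.036 for microglia against the negative fraction. Of 12477 genes tested, limma called 10680 between astrocytes and microglia (5597 higher in astrocytes), 9466 between astrocytes and the negative fraction (4826 higher in astrocytes) and 10449 between microglia and the negative fraction (5017 higher in microglia). The larger side of 2 of these turned with the mean of the probe sets, where 4882 genes were higher and 5265 lower in astrocytes than in microglia and 5383 higher and 4558 lower in microglia than in the negative fraction. With no dim filter these were 6471 and 8260, and 8824 and 6334.

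**Figure D1:**
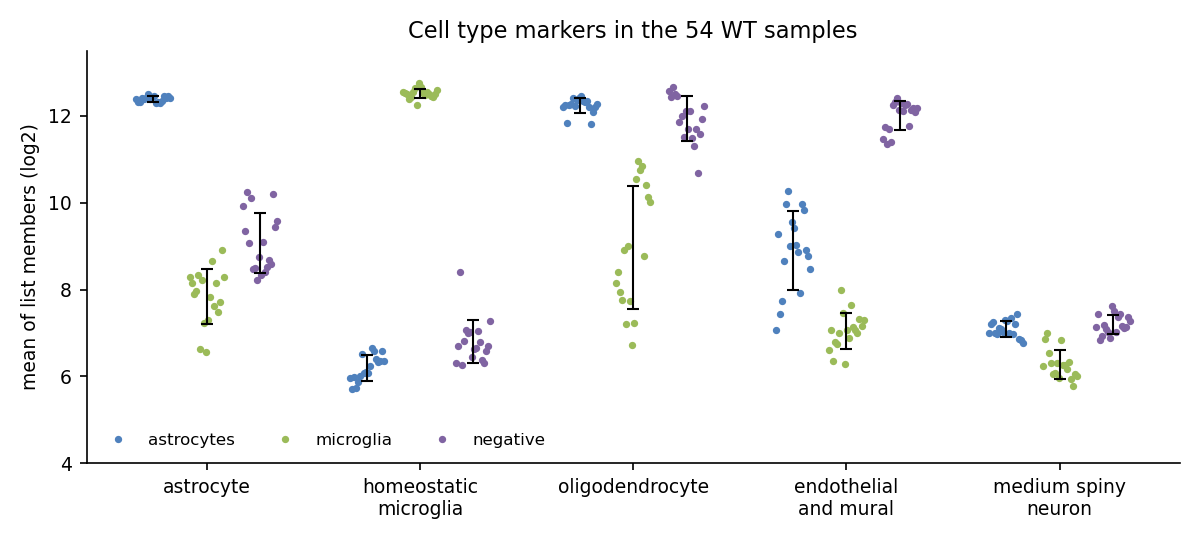
Mean log2 array signal of 5 lists of cell type markers in the WT samples, with 1 point per sample, 18 samples per fraction, and bars at the mean ± SD. Astrocyte markers average 12.39 in the astrocyte fraction, microglia markers 12.52 in microglia and endothelial and mural markers 12.00 in the negative fraction, and oligodendrocyte markers average 12.24 in the astrocyte fraction and 11.94 in the negative fraction.

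Genes changed by genotype were tested at each age in each fraction. Of the genes called in the R6/2 comparisons at 6 weeks and in the zQ175 comparisons of astrocytes and microglia, 100% had every mutant sample on the called side of the WT mean. So did 91.9% of the genes called in R6/2 astrocytes, 98.4% in R6/2 microglia and 83.6% in the R6/2 negative fraction at 12 weeks, and 99.9% in the zQ175 negative fraction at 12 months. The genes were called on these same samples, which favours high shares, and in zQ175 microglia at 6 months 1 gene was called.

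**Figure D2:**
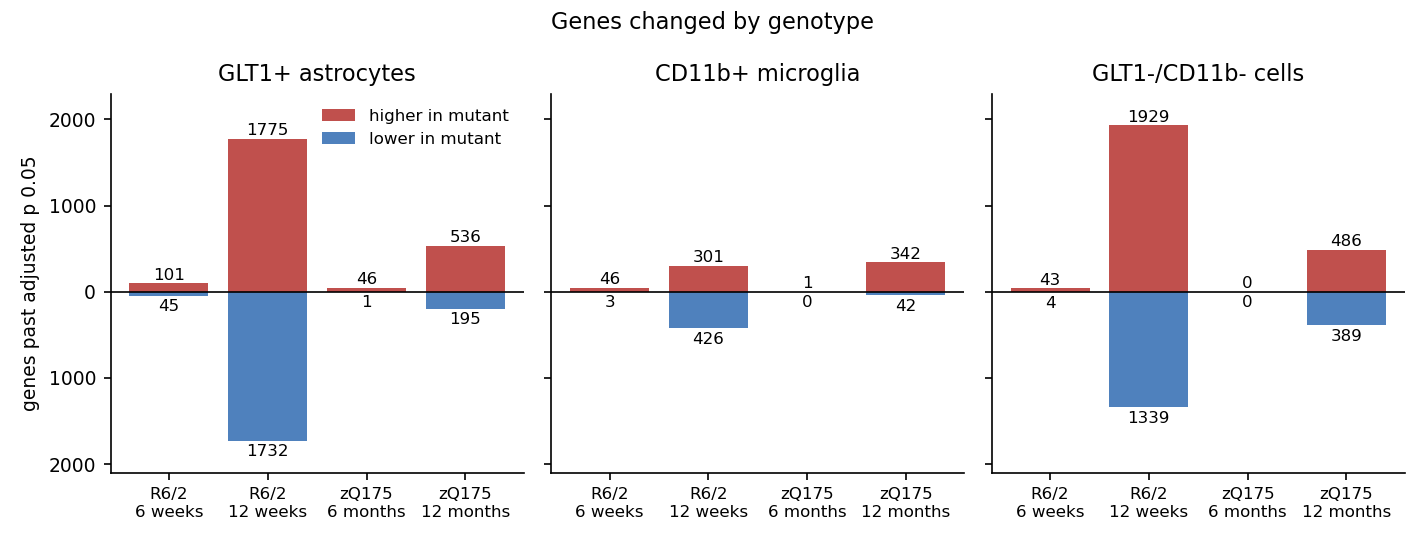
Number of genes called higher (bars upward) and lower (bars downward) in mutant than in WT samples at adjusted p below 0.05, for each fraction, model and age. The counts at 12 weeks in R6/2 are 3507 in astrocytes, 727 in microglia and 3268 in the negative fraction, and those at 12 months in zQ175 are 731, 384 and 875.

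In R6/2 astrocytes at 6 weeks, genes of cholesterol synthesis were lower and interferon-stimulated genes higher than in WT astrocytes. Mvd, an enzyme gene of the mevalonate pathway, was at 9.57 ± 0.41 in 5 R6/2 samples against 10.54 ± 0.17 in 5 WT samples, a log2 fold change of -0.97 ± 0.15 (adjusted p = 0.00107). Idi1, which acts next to it in the pathway, had -0.72 ± 0.12. Usp18, an interferon-induced protease gene that limits interferon signalling, rose by 2.32 ± 0.18 (8.89 ± 0.31 against 6.57 ± 0.27, n = 5 and 5, adjusted p = 4.34e-07), and Oasl2, an antiviral gene, by 2.58 ± 0.31. Cd109, a surface protein gene of the reactive astrocyte list, rose by 2.21 ± 0.21, and Pou4f1, a homeobox gene of sensory neurons, by 1.80 ± 0.20.

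Of 19 cholesterol synthesis genes tested at 6 weeks, 11 were called lower and 16 when adjusted over the list alone (median -0.54). Of 18 interferon-stimulated genes 7 were called higher and 12 over the list alone (median 0.55). Of 8 homeobox developmental regulators, 1 was called higher and 4 over the list alone. These were the 3 lists that fry called, and each kept its call with an estimated correlation (adjusted p = 0.0207, 0.00416 and 0.0105). The reactive astrocyte list had 4 genes called higher, 6 over the list alone, and no shift in 1 direction (adjusted p = 0.179). In all, 146 of 12209 genes were called, 101 higher and 45 lower, 50 of them by more than 2-fold. The count was 96 without WT sample 3 and 86 without R6/2 sample 8.

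At 12 weeks the astrocyte fraction of R6/2 mice differed from WT in 3507 of 12209 genes, 1775 higher and 1732 lower, with 401 of them beyond 2-fold. With no dim filter 1742 were higher and 1785 lower, and with the mean of the probe sets 1493 and 1832. The larger side also turned without R6/2 sample 11, 13, 15, 19 or 21 and without WT sample 12 or 14. Snhg11, a long noncoding RNA host gene, rose by 4.47 ± 0.26 (10.95 ± 0.30 in 6 R6/2 samples against 6.48 ± 0.44 in 5 WT samples, adjusted p = 7.01e-10). Kazald1, which encodes a secreted protein with an insulin-like growth factor binding domain, rose by 3.45 ± 0.14. Bdnf, the neurotrophin gene, fell by 2.43 on the log2 scale (± 0.21), and Kcnk13, a potassium channel gene, fell by 2.35 (± 0.23). Mvd reached 8.62 ± 0.12 against 10.45 ± 0.20, a log2 fold change of -1.83 ± 0.14 (adjusted p = 2.63e-08). Cyp51, a sterol demethylase gene, had -1.33 ± 0.09. Usp18 rose by 3.25 ± 0.17 (10.58 ± 0.24 against 7.33 ± 0.36), and Rtp4, an interferon-induced chaperone gene, by 2.28 ± 0.17.

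Among the genes that serve astrocyte function, Grm3, a metabotropic glutamate receptor gene, was lower in R6/2 astrocytes at 12 weeks (11.55 ± 0.27 in 6 samples against 12.53 ± 0.29 in 5, log2 fold change -0.98 ± 0.14, adjusted p = 5.78e-05). Slc38a3, a glutamine transporter gene, had -0.68 ± 0.10, and Kcnj10, the gene of the potassium channel Kir4.1, -0.26 ± 0.07 (adjusted p = 0.0143). Slc6a11, a GABA transporter gene, had -0.43 ± 0.13, a direction that depended on its probe set, since the mean of its probe sets gave 0.09. Vim, an intermediate filament gene that reactive astrocytes raise, was up by 0.83 ± 0.12, and Fkbp5, a glucocorticoid-induced chaperone gene of the reactive list, by 1.71 ± 0.24. Axl, a phagocytic receptor gene, had -0.66 ± 0.12.

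All 19 tested cholesterol synthesis genes were called lower in the R6/2 astrocyte fraction at 12 weeks (19 over the list alone, median -0.89), and 17 of 18 interferon-stimulated genes higher (17 over the list alone, median 1.31). Both lists kept their call with an estimated correlation, at adjusted p = 0.0475 and 0.015. This fraction also held oligodendrocyte markers, at 12.03 in R6/2 and 12.38 in WT samples. Which of its cells lowered the cholesterol genes, at either age, was not tested. The glutamate and potassium list had 8 of 16 genes called lower and 0 higher (9 over the list alone, median -0.26), and the astrocyte markers 8 lower and 1 higher of 21 (10 and 1 over the list alone, median -0.16). Both shifted downward by fry at adjusted p = 0.00026 and 0.00723, and with an estimated correlation the adjusted p was 0.337 and 0.617. The glutamate and potassium list shares genes with the astrocyte markers, among them Slc1a2 and Kcnj10. Of 8 homeobox regulators 4 were higher (4 over the list alone, fry adjusted p = 7.75e-08, and 0.109 with an estimated correlation), among them Pou4f1 at 2.79 ± 0.19 and Onecut2 at 2.48 ± 0.38. Of the reactive astrocyte genes 7 were higher and 2 lower of 24 (equal over the list alone), of the lipid genes 1 higher and 4 lower of 22 (equal over the list alone), and of the proliferation genes 1 higher of 11. Their shifts by fry, upward, downward and upward, had adjusted p = 0.00723, 0.0156 and 0.00757, and with an estimated correlation adjusted p = 0.645, 0.645 and 0.617.

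Markers of other cell types moved with them in the R6/2 astrocyte fraction. Of 14 oligodendrocyte markers 7 were lower (8 over the list alone, median -0.27), among them Fa2h, a gene of myelin lipid synthesis, at -0.88 ± 0.12. Of 16 medium spiny neuron genes 6 were lower and 1 higher (equal over the list alone, median -0.30), among them Ppp1r1b, the DARPP-32 gene, at -1.28 ± 0.16. By fry these lists shifted at adjusted p = 0.0156 and 0.00723, and with an estimated correlation at adjusted p = 0.645 and 0.617. The endothelial and mural markers averaged 8.92 in R6/2 against 9.64 in WT astrocytes (median log2 fold change -0.74) and did not shift by the test (adjusted p = 0.267). The difference of these means, -0.72, was -0.48 without R6/2 sample 11. With the mean of the endothelial and mural markers as a covariate, a fit chosen after seeing the data, the count of genes stayed within 1.5-fold of 3507.

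Between 6 and 12 weeks the R6/2 effect in astrocytes itself differed for 141 genes, 90 upward and 51 downward. The effect on Kazald1 was larger at 12 weeks by 3.03 ± 0.21 (adjusted p = 5.85e-08) and that on Fxyd6, a gene of a sodium pump regulator, by 2.98 ± 0.33. The effect on Cyp51 was lower by a log2 difference of -0.79 ± 0.13. Of the cholesterol list, 4 genes differed between ages and 13 over the list alone (median -0.37), and of the interferon list 3 and 7 (median 0.57). Both shifted by fry at adjusted p = 0.0103, and with an estimated correlation the adjusted p was 0.178 for both. Of the 101 genes called higher at 6 weeks, 94 were also called higher at 12 weeks (14.7 expected if the calls were independent), and 44 of the 45 called lower were also lower (6.38 expected). The count of 141 depended on single samples. It was 60, 68 and 65 without WT samples 2, 4 and 5 and 64, 82, 83 and 53 without R6/2 samples 6, 7, 9 and 10. It was 76, 83 and 89 without WT samples 16, 18 and 20. With the Y-linked mean as a covariate it was 89, and 20 in a fit chosen after seeing the data, without WT samples 12 and 20, which lack Y-linked expression.

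In zQ175 astrocytes at 6 months, 47 of 12380 genes were called, 46 of them higher. Abhd1, a gene of an alpha/beta hydrolase, was at 10.33 ± 0.26 in 4 zQ175 samples against 8.10 ± 0.20 in 4 WT samples, a log2 fold change of 2.23 ± 0.14 (adjusted p = 2.27e-06). Uchl1, a neuronal deubiquitinase gene, rose by 1.86 ± 0.15, and S100b, the gene of a calcium-binding protein abundant in astrocytes, by 0.55 ± 0.06. The 1 gene called lower was the unannotated A830082N09Rik (-0.76 ± 0.14), a call lost without WT sample 22, 23 or 25 or zQ175 sample 26, 27 or 29 (fold changes from -0.70 to -0.79). No list shifted by fry. The count was 30 without WT sample 22, and 29, 25 and 27 without zQ175 samples 26, 27 and 28.

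At 12 months, 731 genes were called in zQ175 astrocytes, 536 higher and 195 lower, and 160 by more than 2-fold. Tnfrsf13c, a cytokine receptor gene, rose by 3.89 ± 0.25 (10.22 ± 0.20 in 4 zQ175 samples against 6.33 ± 0.49 in 4 WT samples, adjusted p = 3.47e-07), Snhg11 by 3.88 ± 0.37 and Uchl1 by 2.48 ± 0.15. S100b was higher by 0.64 ± 0.06 and Nkx2-2, a homeobox gene of the oligodendrocyte lineage, by 0.57 ± 0.08. Gpr3, a receptor gene, had -1.21 ± 0.18, and the clock gene Per1 had -1.19 ± 0.24. Idi1 was lower by a log2 fold change of -0.34 ± 0.08 (adjusted p = 0.0195), a call lost without zQ175 sample 32 or 33 (-0.31 and -0.33). Mx2, an antiviral gene, was higher by 0.74 ± 0.19, a call lost without WT sample 34 or 35 (0.68 in both cases). The count was 335 and 357 without zQ175 samples 31 and 32, and 367 and 451 without WT samples 34 and 35.

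By list at 12 months, 2 of 15 glutamate and potassium genes were called lower in zQ175 astrocytes and 6 over the list alone (median -0.22, fry adjusted p = 0.000203). Of 21 astrocyte markers 2 were lower and 1 higher (7 and 1 over the list alone, median -0.13, adjusted p = 0.00311). With an estimated correlation these had adjusted p = 0.0503 and 0.106, and both lists hold Slc1a2 and Kcnj10 among other shared genes. The heat shock list had 2 genes lower of 20 and 8 over the list alone (adjusted p = 0.011, and 0.191 with an estimated correlation), among them Dnajb1, a chaperone gene, at -0.52 ± 0.12, whose call was lost without zQ175 sample 32 (-0.43) or WT sample 35 (-0.50). Of 7 homeobox regulators 2 were higher (adjusted p = 0.00451, and 0.377 with an estimated correlation). Cholesterol synthesis genes were lower in 3 of 19 cases and 4 over the list alone (median -0.15), interferon-stimulated genes higher in 3 of 18 and 6 over the list alone (median 0.38), and cytokine and NF-kB genes lower in 0 of 9 and 3 over the list alone (median -0.34). Each of the last 3 lists shifted by fry at adjusted p = 0.049, and with an estimated correlation at adjusted p = 0.377, 0.401 and 0.347.

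A change of the zQ175 effect between 6 and 12 months was called for 1 astrocyte gene by limma, Fam160b2 (-1.54 ± 0.15, adjusted p = 0.000412), with 562 genes at an unadjusted p below 0.05. The count was 2 without WT sample 35. Of the 46 genes called higher at 6 months, 43 were called higher at 12 months (1.99 expected if independent). The largest differences by p among genes not called were those of Gng3 (1.13 ± 0.22) and Cdh6 (0.92 ± 0.18), each at adjusted p = 0.512.

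In R6/2 microglia at 6 weeks, interferon-stimulated genes were higher than in WT microglia. Ifit3, a gene of an antiviral protein that binds RNA, rose by 2.21 ± 0.13 (10.95 ± 0.25 in 5 R6/2 samples against 8.74 ± 0.10 in 5 WT samples, adjusted p = 2.62e-09), and Rtp4 by 2.27 ± 0.13. Usp18 was higher by 2.25 ± 0.15. Ctxn1, a neuronal membrane protein gene, was 1 of the 3 genes called lower, at -1.46 ± 0.23. Of 20 interferon-stimulated genes 14 were called higher, 18 over the list alone (median 1.46, fry adjusted p = 3.76e-09, and 2.6e-05 with an estimated correlation). Medium spiny neuron genes shifted downward, with 1 of 15 called and 8 over the list alone (median -0.53, adjusted p = 0.0156, and 0.23 with an estimated correlation). In all 49 of 11958 genes were called, 46 higher and 3 lower. All 46 were called higher again at 12 weeks (1.16 expected if independent, though the ages share an estimate of the spread, which favours overlap).

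At 12 weeks, R6/2 microglia added genes of the disease-associated microglia list. Cst7, a cystatin gene that activated microglia induce, was at 10.78 ± 0.30 in 6 R6/2 samples against 8.01 ± 0.48 in 5 WT samples, a log2 fold change of 2.77 ± 0.21 (adjusted p = 1.42e-08). Axl, a gene of a receptor for dying cells, rose by 2.40 ± 0.22, Clec7a, the gene of the receptor dectin-1, by 1.84 ± 0.17, and Apoe, the apolipoprotein E gene, by 1.44 ± 0.14. The interferon genes Oas1a and Usp18 rose by 3.21 ± 0.14 and 3.10 ± 0.14, and Cxcl1, a chemokine gene, by 2.27 ± 0.36. Nrarp, a Notch target gene, had -1.47 ± 0.15, and the heat shock gene Hspa1a had -0.98 ± 0.20.

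Of 20 interferon-stimulated genes 19 were called higher at 12 weeks (19 over the list alone, median 2.27), and of 21 disease-associated microglia genes 11 (11 over the list alone, median 0.39). Both lists kept their call with an estimated correlation, at adjusted p = 0.000125 and 0.000272. The cytokine and NF-kB list had 7 genes higher and 1 lower of 19 (11 and 1 over the list alone), the lipid list 4 higher of 22 (5 over the list alone) and the medium spiny neuron list 4 lower of 15 (5 over the list alone). Each of these had a fry adjusted p = 0.0132, and with an estimated correlation adjusted p = 0.188, 0.188 and 0.29. The lipid list shares Apoe and Lpl with the disease-associated list. In all, 727 of 11958 genes were called, 301 higher and 426 lower, 168 of them by more than 2-fold. The excess of lower calls depended on the fit: 198 were higher and 161 lower with only the 2 groups compared, 285 and 284 with arrayWeights, and 313 and 274 without WT sample 16. The count was 461 with the Y-linked mean as a covariate (212 higher and 249 lower). Without WT samples 12 and 20, which lack Y-linked expression, it was 475 (213 and 262), in a fit chosen after seeing the data.

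The R6/2 effect in microglia differed between 6 and 12 weeks for 30 genes, 24 upward and 6 downward. Cst7 differed by 2.68 ± 0.30 (adjusted p = 0.000237), Lpl, a lipoprotein lipase gene, by 2.30 ± 0.35 and Oas1a by 1.40 ± 0.20. The disease-associated list had 6 genes called and 11 over the list alone (median 0.41, fry adjusted p = 1.38e-06), the interferon list 1 called and 15 over the list alone with 1 opposite (median 0.69, adjusted p = 0.00566), and both kept the call with an estimated correlation (adjusted p = 0.000236 and 0.0445). The lipid list, which shares Apoe and Lpl with the disease-associated list, had 2 called and 4 over the list alone (adjusted p = 0.0408, and 0.136 with an estimated correlation). The count of 30 was 50 without WT sample 14 and 46 without WT sample 16.

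**Figure D3:**
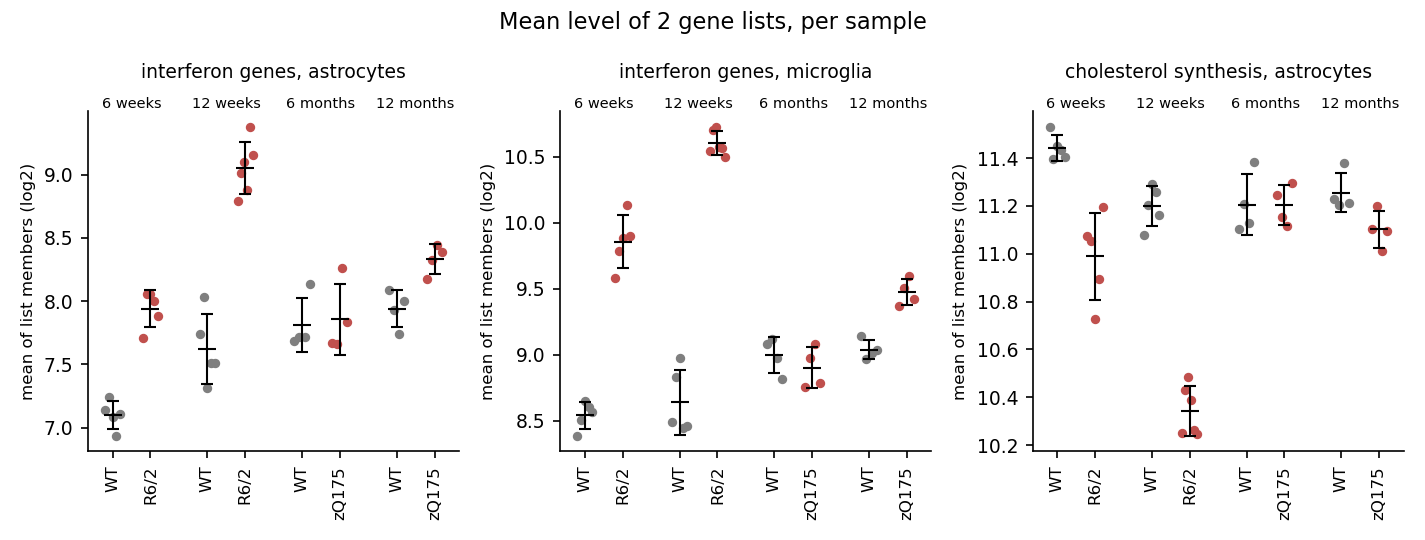
Mean log2 array signal per sample of the interferon-stimulated genes in astrocytes and in microglia and of the cholesterol synthesis genes in astrocytes, for WT and mutant samples at each age, with bars at the mean ± SD. At 12 weeks the interferon list averages 9.05 in R6/2 against 7.62 in WT astrocytes and 10.60 against 8.64 in microglia, and the cholesterol list 10.34 against 11.20 in astrocytes.

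In zQ175 microglia at 6 months, limma called 1 gene of 12201, Abhd1 (8.86 ± 0.24 in 4 zQ175 samples against 7.41 ± 0.24 in 4 WT samples, log2 fold change 1.44 ± 0.15, adjusted p = 0.00189), with 471 genes at an unadjusted p below 0.05. The count was 2 without WT sample 22 or without WT sample 24, and no list shifted by fry. Etl4 (2.17 ± 0.38) and C1ql3 (1.30 ± 0.23), the next by p, were not called (adjusted p = 0.176).

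At 12 months, 384 genes were called in zQ175 microglia, 342 higher and 42 lower. Cst7 was at 11.73 ± 0.12 in 4 zQ175 samples against 10.29 ± 0.24 in 4 WT samples, a log2 fold change of 1.44 ± 0.21 (adjusted p = 0.00325). Apoe rose by 1.01 ± 0.15 and Lpl by 0.89 ± 0.13. Mamdc2, a gene of an extracellular matrix protein, rose by 3.88 ± 0.47 (8.40 ± 0.38 against 4.53 ± 0.80), and Fabp5, a fatty acid binding protein gene, by 1.06 ± 0.15. Retnla, a gene of alternatively activated macrophages, had -1.96 ± 0.24. Mag, a myelin glycoprotein gene, was higher by 1.29 ± 0.25, and Cspg4, a gene of oligodendrocyte precursors, by 1.95 ± 0.32.

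Of the disease-associated list, 9 of 21 genes were called higher in zQ175 microglia at 12 months and 10 over the list alone (median 0.05 and mean 0.58, fry adjusted p = 0.00106, and 0.0738 with an estimated correlation). The interferon list had 3 of 20 higher and 10 over the list alone (median 0.47) and the oligodendrocyte precursor list 2 of 7 and 4 over the list alone (median 0.89). With an estimated correlation these 2 lists also had adjusted p = 0.0738. Of 14 oligodendrocyte markers 3 were called higher and 12 over the list alone (median 0.97, fry adjusted p = 0.0281), of 22 lipid genes 5 and 7 (adjusted p = 0.0277), and of 17 proliferation genes 1 and 6 (adjusted p = 0.0317). With an estimated correlation these had adjusted p = 0.235, 0.251 and 0.235. Apoe and Lpl are on both the disease-associated and the lipid list. Oligodendrocyte markers averaged 10.80 in zQ175 against 9.83 in WT microglia and endothelial and mural markers 8.33 against 7.20. Single samples carried much of both differences: that of the oligodendrocyte markers fell from 0.97 to 0.62 without WT sample 34, and that of the endothelial and mural markers from 1.13 to 0.60 without zQ175 sample 31. With the mean of these markers as a covariate, a fit chosen after seeing the data whose covariate itself differed between the genotypes, limma called 0 genes, beside 384 without it and 1834 at an unadjusted p below 0.05. The count of 384 was 155, 190 and 164 without zQ175 samples 31, 32 and 33, and 213 without WT sample 34.

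The zQ175 effect in microglia did not differ between 6 and 12 months for any gene by limma (0 called, 841 at an unadjusted p below 0.05), and the count was 1 without WT sample 24. The interferon list shifted upward between the ages, with 0 genes called and 2 over the list alone of 20 (median 0.60, fry adjusted p = 0.00869, and 0.0362 with an estimated correlation). The smallest p-values were those of Mamdc2 (4.17 ± 0.66) and Plekhg1 (2.01 ± 0.33), each with adjusted p = 0.137.

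In the negative fraction of R6/2 mice at 6 weeks, 47 of 12480 genes were called, 43 higher and 4 lower. Eya4, a transcriptional coactivator gene, rose by 1.93 ± 0.23 (7.78 ± 0.28 in 5 R6/2 samples against 5.85 ± 0.25 in 5 WT samples, adjusted p = 0.000368), and Mmp2, a matrix protease gene, by 1.79 ± 0.24. Usp18 was higher by 1.01 ± 0.17. Nppc, a natriuretic peptide gene, had -1.05 ± 0.18. No list shifted by fry: the interferon list had 2 of its genes called and 8 over the list alone (adjusted p = 0.0727), and the cholesterol list 1 lower and 3 over the list alone (adjusted p = 0.0515). The count was 29, 27, 31, 23 and 26 without WT samples 1, 2, 3, 4 and 5, and 26 and 22 without R6/2 samples 8 and 9. Of the 43 genes called higher, 41 were so at 12 weeks (6.65 expected if independent).

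At 12 weeks the R6/2 negative fraction carried higher levels of astrocyte genes. Aldoc, an aldolase gene enriched in astrocytes, was at 12.09 ± 0.36 in 6 R6/2 samples against 8.08 ± 0.60 in 5 WT samples, a log2 fold change of 4.01 ± 0.28 (adjusted p = 5.4e-09), and Aqp4, the gene of the water channel of astrocyte endfeet, rose by 4.35 ± 0.49. Clu, the clusterin gene, rose by 2.66 ± 0.21, and Serpina3n, a protease inhibitor gene of reactive astrocytes, by 4.60 ± 0.40. Scel, a sciellin gene, had the largest rise, 5.22 ± 0.32. Tagln, an actin-binding protein gene of mural cells, was lower by a log2 fold change of -0.86 ± 0.15, and Ccl11, a chemokine gene, by -2.59 ± 0.31.

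Of 21 astrocyte markers 18 were called higher (18 over the list alone, median 1.99), of 16 glutamate and potassium genes 9 higher and 1 lower (equal over the list alone, median 0.41), of 17 glycolysis genes 6 higher and of 10 oligodendrocyte precursor markers 7 higher and 1 lower (8 and 1 over the list alone, median 0.69). These 4 lists shifted upward by fry at adjusted p = 1.74e-05, 0.000185, 0.000185 and 0.000936, and with an estimated correlation each had adjusted p = 0.426. Lipid genes were higher in 10 of 22 cases and lower in 2 (10 and 4 over the list alone, adjusted p = 0.00128), and interferon-stimulated genes higher in 10 of 18 (10 over the list alone, median 0.51, adjusted p = 0.00245), with Usp18 at 1.09 ± 0.17. With an estimated correlation both had adjusted p = 0.426. Downward shifts by fry were found for 5 lists, each also at adjusted p = 0.426 with an estimated correlation. Border macrophage and blood cell markers were lower in 5 of 6 cases (5 over the list alone, median -1.42, adjusted p = 0.000378), cytokine and NF-kB genes in 4 of 13 (4 over the list alone, median -0.70, adjusted p = 0.00273), ependymal markers in 1 of 10 (adjusted p = 0.00502), endothelial and mural markers in 6 of 18 (9 over the list alone, median -0.49, adjusted p = 0.0351) and complement genes in 2 of 6 (adjusted p = 0.0416). Homeobox regulators had 2 higher and 1 lower of 7, and 2 of each over the list alone (fry adjusted p = 0.0225 upward, and 0.775 with an estimated correlation). The reactive astrocyte list had 3 higher and 12 lower of 25 and no shift by fry (adjusted p = 0.0568), though its genes changed in either direction (adjusted p = 1.24e-09 by the mixed test).

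In all, 3268 of 12480 genes were called in the R6/2 negative fraction at 12 weeks, 1929 higher and 1339 lower, 1142 by more than 2-fold. Of these 1 was sex-linked, Eif2s3y (3.22 ± 1.17, adjusted p = 0.0467), and 2 of the 5 WT samples, 12 and 20, lacked Y-linked expression. That call was lost without R6/2 sample 11, 13, 15 or 17 (3.10, 3.06, 3.16 and 3.16) and without WT sample 12 or 20 (2.16 and 2.02). With the mean of the astrocyte markers as a covariate, a fit chosen after seeing the data, 122 genes were called. That covariate itself parted the genotypes, at 10.29 ± 0.49 in R6/2 and 8.46 ± 0.20 in WT samples. The R6/2 effect differed between ages for 530 genes, 471 upward and 59 downward, a count that was 900 without R6/2 sample 11. Aldoc differed by 3.55 ± 0.41 (adjusted p = 6.62e-05). Of the astrocyte markers 10 of 21 differed and 15 over the list alone (median 1.45). The counts were 4 and 8 for the glutamate and potassium list, 2 and 8 with 1 opposite for the oligodendrocyte precursor list, and 2 and 5 for the cholesterol list. By fry the first 3 had adjusted p = 0.00835, the cholesterol list 0.0105, and the border macrophage and blood cell list, with 1 gene lower and 2 over the list alone, 0.0359. All 5 had adjusted p = 0.271 with an estimated correlation.

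**Figure D4:**
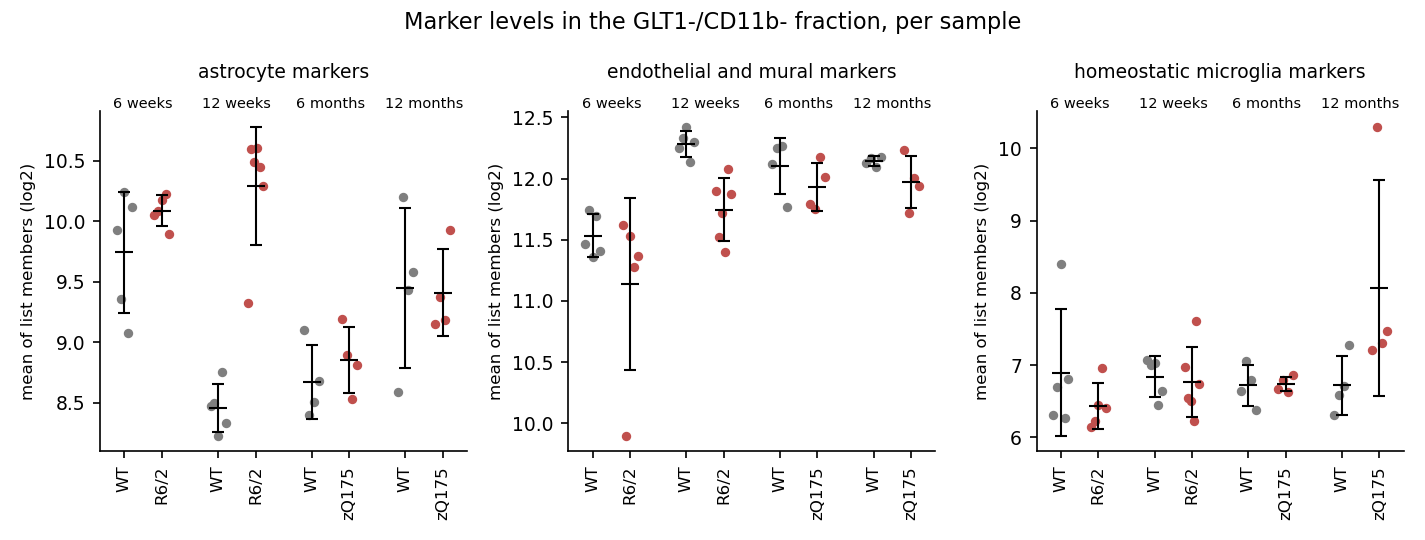
Mean log2 array signal per sample of astrocyte, endothelial and mural, and homeostatic microglia markers in the negative fraction, for WT and mutant samples at each age, with bars at the mean ± SD. Astrocyte markers average 10.29 in R6/2 against 8.46 in WT samples at 12 weeks and 9.41 in zQ175 against 9.45 in WT samples at 12 months, and zQ175 sample 31 at 12 months lies apart in microglia markers at 10.30.

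The zQ175 negative fraction at 6 months had 0 of 12628 genes called by limma, with 349 at an unadjusted p below 0.05. Abhd1 (1.33 ± 0.20) and Acan, the gene of the matrix proteoglycan aggrecan, came closest, each with adjusted p = 0.0583. At 12 months Cnmd, the gene of the cartilage matrix protein chondromodulin, was at 9.60 ± 0.38 in 4 zQ175 samples against 5.05 ± 0.93 in 4 WT samples. Its log2 fold change was 4.55 ± 0.42 (adjusted p = 5.38e-05), and Acan rose by 4.48 ± 0.23. Gpr17, a receptor gene of oligodendrocyte precursors, rose by 2.14 ± 0.33 and Serpina3n by 2.70 ± 0.44. Scn4b, a sodium channel gene of medium spiny neurons, had -0.81 ± 0.11 and Npy1r, a neuropeptide receptor gene, -2.23 ± 0.30.

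Of 10 oligodendrocyte precursor markers 3 were called higher in the zQ175 negative fraction at 12 months and 5 over the list alone (median 0.95, fry adjusted p = 0.0484). Of 17 medium spiny neuron genes 4 were lower (4 over the list alone), with a median of 0.05, a mean of -0.11 and a downward shift by fry (adjusted p = 0.0484). With an estimated correlation both lists had adjusted p = 0.911. Homeostatic microglia markers had 2 genes higher and 1 lower of 11 (6 and 1 over the list alone, median 1.49) without a shift by fry (adjusted p = 0.441), and zQ175 sample 31 held these markers at 10.30 against 7.33 in the other 3 samples. In all 875 of 12628 genes were called, 486 higher and 389 lower. The larger side turned with the dim filter at the 60th percentile (335 higher and 397 lower), the mean of the probe sets (355 and 435), arrayWeights (366 and 395) and without zQ175 sample 30 (147 and 151) or 33 (717 and 843). The count was 298, 169 and 1560 without zQ175 samples 30, 32 and 33, and 168, 172 and 525 without WT samples 34, 35 and 36.

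Between 6 and 12 months the zQ175 effect in the negative fraction differed for 4 genes by limma, with 2716 at an unadjusted p below 0.05. These were Acan (2.98 ± 0.32), Rap1gap, a gene of a GTPase activator (2.59 ± 0.37, adjusted p = 0.0226), Frzb, a Wnt antagonist gene (2.42 ± 0.36), and Lox, a lysyl oxidase gene (-1.58 ± 0.24). The calls of Rap1gap, Frzb and Lox were lost without WT sample 24, 35 or 36 or zQ175 sample 27, 28 or 30. The call of Rap1gap was also lost without zQ175 sample 29, that of Frzb without WT sample 23 or zQ175 sample 32, and that of Lox without zQ175 sample 29 or 31. Their values in these runs reached at most 2.64 for Rap1gap, 2.47 for Frzb and -1.63 for Lox. The count was 10, 1 and 7 without WT samples 22, 24 and 25, 34, 1, 1, 2, 1 and 25 without zQ175 samples 26, 27, 28, 29, 30 and 33, and 1, 1 and 9 without WT samples 35, 36 and 37.

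The samples of the 2 models differed in line, in age and in Xist, a gene that cells with 2 X chromosomes express. Its group means ran from 4.12 to 5.27 in the zQ175 and WT groups at 6 and 12 months, where Y-linked means ran from 8.81 to 9.58. In the R6/2 and WT groups at 6 and 12 weeks the Xist means ran from 10.55 to 12.27. Y-linked means there ran from 8.30 to 8.65 in the R6/2 groups and from 6.21 to 8.54 in the WT groups. These samples thus expressed both Xist and Y-linked genes, apart from WT samples 3, 12 and 20. The oldest groups of both models were then compared over the genes called in R6/2 at 12 weeks. Across 3450 such genes in astrocytes, which are not independent replicates, the R6/2 and zQ175 fold changes had Pearson r = 0.485 and Spearman rho = 0.449, and 67.8% of the genes had the same sign. In microglia r was 0.543 and rho 0.482 over 708 genes with 71.2% of the same sign, and in the negative fraction r was 0.484 and rho 0.442 over 3167 genes with 68.6% of the same sign. An exact one-sided permutation of the zQ175 and WT labels at 12 months (70 relabellings, smallest possible p = 0.0143) gave p = 0.0714 in astrocytes, 0.0429 in microglia and 0.143 in the negative fraction, or 0.107, 0.107 and 0.143 after adjustment over the 3, so none passed over these genes. Over all genes tested in both models, astrocytes passed (r = 0.361, p = 0.0143, the smallest possible, adjusted p = 0.0429), and microglia (r = 0.266, adjusted p = 0.0643) and the negative fraction (r = 0.349, adjusted p = 0.129) did not. With no dim filter, with the mean of the probe sets or with quantile normalization the adjusted p in astrocytes was 0.107. In microglia the unadjusted p was no longer below 0.05 without WT sample 18 (r = 0.522) or without zQ175 sample 30 (0.498) or 33 (0.528), and in astrocytes it was below 0.05 without WT sample 34 (0.541). Genes called higher in both models numbered 203 in astrocytes, 42 in microglia and 231 in the negative fraction (74.4, 6.38 and 71.7 expected if the calls were independent), and genes called lower in both 94, 8 and 133 (27.5, 1.45 and 41.6 expected).

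**Figure D5:**
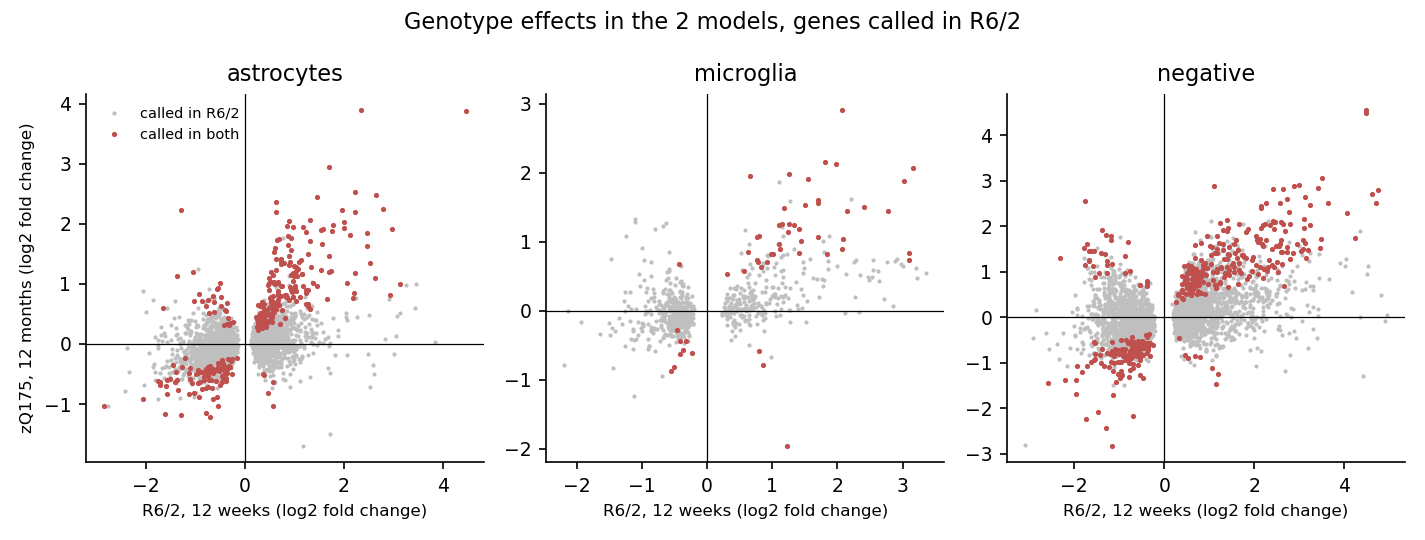
Log2 fold change (mutant minus WT) in zQ175 at 12 months (vertical axis) against that in R6/2 at 12 weeks (horizontal axis) for the genes called in R6/2, in each fraction, with 1 point per gene and genes called in both models in red. Pearson r is 0.485 in astrocytes, 0.543 in microglia and 0.484 in the negative fraction, where exact permutation p-values are 0.0714, 0.0429 and 0.143.

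The difference between the R6/2 effect at 12 weeks and the zQ175 effect at 12 months was also tested gene by gene, in a contrast chosen after seeing the data. In astrocytes it was called for 1244 of 12270 genes, 472 more positive and 772 more negative in R6/2. Usp18 differed by 2.28 ± 0.34 (adjusted p = 7.33e-05), Idi1 by -1.11 ± 0.15 and Fa2h by -0.92 ± 0.20. Of the cholesterol list 15 of 19 genes were more negative in R6/2 (17 over the list alone, median -0.75) and of the interferon list 12 of 18 more positive (13 over the list alone, median 1.03). Both lists kept their call with an estimated correlation (adjusted p = 0.0266 for both). The cytokine and NF-kB list, with 2 of 6 genes called, had fry adjusted p = 0.00296 and 0.144 with an estimated correlation, and the oligodendrocyte markers, with 5 of 14 lower and 10 over the list alone, 0.0223 and 0.472. The count was 788 without zQ175 sample 31 and 765 without WT sample 34.

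In microglia the models differed for 232 of 12108 genes, 84 more positive and 148 more negative in R6/2. Oas1a differed by 2.59 ± 0.23 (adjusted p = 1.24e-08) and Cst7 by 1.33 ± 0.31, and Retnla by 3.19 ± 0.35. The interferon list had 16 of 20 genes more positive in R6/2 (18 over the list alone with 1 opposite, median 1.56, adjusted p = 9.47e-11, and 3.76e-06 with an estimated correlation). Medium spiny neuron genes, pan-neuronal markers and cholesterol genes shifted downward (medians -0.90, -0.72 and -0.35) at fry adjusted p = 0.00728, 0.0291 and 0.0315, and with an estimated correlation at 0.18, 0.279 and 0.287. Of their genes 1, 1 and 0 were called and 6, 2 and 1 over the list alone. The count was 126 without zQ175 sample 31 and 122 without WT sample 34, where 62 genes were more positive and 60 more negative.

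In the negative fraction the models differed for 1347 of 12541 genes, 808 more positive and 539 more negative in R6/2. Aldoc differed by 2.88 ± 0.54 (adjusted p = 0.000791) and Clu by 1.98 ± 0.31, and Cd79a, a B cell receptor gene, by -2.83 ± 0.52. Of 21 astrocyte markers 14 were more positive in R6/2 (15 over the list alone, median 1.97, fry adjusted p = 0.00158, and 0.55 with an estimated correlation). The border macrophage and blood cell list had 3 of 8 genes more negative (6 over the list alone) and the complement list 1 of 6 (2 over the list alone), each at fry adjusted p = 0.0348 and 0.843 with an estimated correlation. The count was 2445 without R6/2 sample 21, 893, 635 and 2106 without zQ175 samples 30, 32 and 33, and 798 without WT sample 35.

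Htt itself, the gene that carries the zQ175 mutation, was measured at 8.83 ± 0.18 in 6 R6/2 astrocyte samples at 12 weeks against 8.56 ± 0.15 in 5 WT samples, a log2 fold change of 0.27 ± 0.09 (adjusted p = 0.0329). That call was lost without R6/2 sample 11, 17 or 21 or WT sample 12, 16 or 20, where the fold change lay at 0.27, 0.20, 0.27, 0.20, 0.27 and 0.28. It was also lost with the Y-linked mean as a covariate (0.17, adjusted p = 0.226). In zQ175 astrocytes Htt had -0.44 ± 0.20 at 6 months (adjusted p = 0.665) and -0.50 ± 0.20 at 12 months (adjusted p = 0.161), neither called, and the models differed by 0.77 ± 0.20 (adjusted p = 0.0136). In microglia and the negative fraction Htt was called in no comparison. Its log2 fold changes at the older ages were -0.04 and -0.28 in microglia and 0.35 and -0.00 in the negative fraction, for R6/2 and zQ175 in that order. Immediate early genes and oxidative phosphorylation genes shifted in no mutant comparison, with fry adjusted p of 0.0969 and 0.111 at the lowest, and neither did homeostatic microglia markers (0.054) or sex-linked genes (0.0508).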

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

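Tests chosen only after the result was seen were those of fewer cells of the main type, of the astrocyte share that each marker needs, of microglial RNA and of a linked locus, the fit without the 2 WT samples that lack Y-linked expression, and the contrasts between the models. The tests of a larger astrocyte share, of WT samples of a single sex and of Abhd1 were chosen once the pattern was seen, before the values that decide them. The gene lists, the comparisons within each model and between WT fractions, and the counts of other splits for these comparisons were chosen before the data were examined.

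Single samples lay far from the others of their group in 19 of 192 tests over 8 measures, where chance alone gives about 1 in 20, or 9.6. In astrocytes, Htt was at 9.17 in R6/2 sample 17 at 12 weeks (mean of the others 8.76), 8.29 in WT sample 12 at 12 weeks (8.62) and 9.14 in WT sample 36 at 12 months (8.61). Slc1a2 was at 9.64 in microglia of WT sample 23 at 6 months (9.07). The Y-linked mean of WT sample 2 at 6 weeks was 7.52 in astrocytes (8.80) and 7.49 in microglia (8.71). Astrocyte markers were at 9.33 in the negative fraction of R6/2 sample 11 at 12 weeks (10.49). Homeostatic microglia markers were at 8.40 in the negative fraction of WT sample 3 at 6 weeks (6.52) and 10.30 in that of zQ175 sample 31 at 12 months (7.33). In astrocytes these markers were at 6.20 in R6/2 sample 6 at 6 weeks (5.88), 6.51 in WT sample 14 at 12 weeks (6.06) and 6.58 in WT sample 36 at 12 months (6.35). Oligodendrocyte markers were at 11.84 in astrocytes of WT sample 3 at 6 weeks (12.24). Endothelial and mural markers were at 7.25 in microglia of R6/2 sample 8 at 6 weeks (6.52), 9.90 in the negative fraction of R6/2 sample 7 at 6 weeks (11.45) and 7.58 in astrocytes of zQ175 sample 31 at 12 months (9.07). Medium spiny neuron genes were at 6.24 in microglia of R6/2 sample 9 at 6 weeks (5.97), 6.37 in microglia of zQ175 sample 26 at 6 months (5.93) and 7.43 in astrocytes of WT sample 34 at 12 months (6.82).

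Effects that differed between groups by a test of the difference itself were the R6/2 effects at 6 and 12 weeks (141 genes in astrocytes, 30 in microglia and 530 in the negative fraction) and the zQ175 effects at 6 and 12 months (1 gene in astrocytes and 4 in the negative fraction). The effects of R6/2 at 12 weeks and zQ175 at 12 months differed for 1244, 232 and 1347 genes in astrocytes, microglia and the negative fraction. The models differ in mouse line, in age and in Xist (means of 5.26 and 5.01 in zQ175 and WT astrocytes at 12 months against 12.20 and 12.15 in R6/2 and WT astrocytes at 12 weeks). Y-linked means of these groups were 8.93 and 9.01 against 8.54 and 6.21. The contrast does not separate line, age and sex.

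Other splits of the same samples into groups of the same sizes show where chance can be excluded. For the R6/2 comparisons, 1 of 100 splits, the real one, called as many genes at 6 weeks in astrocytes (146 genes, highest other 4), microglia (49, highest other 1) and the negative fraction (47, highest other 2). The same held at 12 weeks in astrocytes (3507, highest other 2678), microglia (727, highest other 293) and the negative fraction (3268, highest other 2463). For the difference between ages, 1 of 100 splits called as many in astrocytes (141, highest other 2), 2 of 100 in microglia (30, highest other 63) and 4 of 100 in the negative fraction (530, highest other 1695). For zQ175, 1 of 35 splits called as many in astrocytes at 6 months (47, highest other 3) and 12 months (731, highest other 416) and in the negative fraction at 12 months (875, highest other 1). For the difference between the models, 1 of 100 splits called as many in astrocytes (1244, highest other 643), 2 of 100 in microglia (232, highest other 1199) and 2 of 100 in the negative fraction (1347, highest other 1528). With the fractions exchanged among WT samples of 1 number, 1 of 100 splits called as many between astrocytes and microglia (10680, highest other 6173), astrocytes and the negative fraction (9466, highest other 3305) and microglia and the negative fraction (10449, highest other 4348). In these cases the share was under 0.05, with no adjustment over the counts. For the comparisons of mutant with WT samples and of WT fractions, chance can be excluded at that level. For the differences between ages and between models the splits cannot decide. Exchanging the labels there also removes the genotype effect at each age, so equal effects were not what was tested.

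Chance was not excluded for zQ175 microglia, where 2 of 35 splits called as many genes at 6 months (1 gene, highest other 1) and 2 of 35 at 12 months (384, highest other 539). For the zQ175 difference between ages the splits cannot decide, since exchanging the labels also removes the genotype effect at each age. As many genes were called by 9 of 100 splits in astrocytes (1 gene, highest other 58) and 6 of 100 in the negative fraction (4, highest other 337). For the zQ175 negative fraction at 6 months the splits cannot decide. Limma called 0 genes there, beside 349 at an unadjusted p below 0.05, a count that all 35 splits reach by definition (highest other 4). The same holds for the zQ175 difference between ages in microglia. Limma called 0 genes, beside 841 at an unadjusted p below 0.05, which all 100 splits reach by definition (highest other 526). Some splits for a difference between effects called several times the real count, which points to a structure of the samples. Genotype itself may be part of it. The split with 1695 genes against 530 left all 6 R6/2 samples at 12 weeks in the R6/2 group and 2 of 5 at 6 weeks, and those with 337 against 4 and 58 against 1 exchanged all 4 zQ175 samples at 12 months with WT samples. The splits with 526 against 0 and 1199 against 232 left 2 of the 4 zQ175 samples at 12 months in the zQ175 group, and the source of their counts was not tested.

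Astrocyte markers rose in the negative fraction of R6/2 mice at 12 weeks, a gate meant to exclude GLT1-positive cells, with 18 of 21 called (median 1.99). Against the other genes the list did not pass with an estimated correlation (camera adjusted p = 0.426). Of these 21 markers, 8 are also on the glutamate and potassium list. Fewer cells of the main type of this fraction alone would raise the markers of all other types alike. The astrocyte median exceeded those of oligodendrocyte markers (-0.18) and medium spiny neuron genes (-0.46) by at least 2.165. These 2 lists cannot decide it, since in WT samples at 12 weeks oligodendrocyte markers were bright here (11.84) and medium spiny neuron genes dim (7.23). Oligodendrocyte precursor markers, not in that test, shifted upward and endothelial and mural markers downward, so such a loss stays open as part of the rise. A larger share of typical GLT1-positive astrocytes in this gate may account for the rise, since 94.3% of the 244 genes at least 8-fold brighter in WT astrocytes had a fold change above 0 (200 called higher and 2 lower, median 1.86). These genes were picked in part by a low level in the same WT samples, which favours values above 0. In the zQ175 negative fraction at 12 months, where astrocyte markers averaged 9.41 against 9.45 in WT samples, 146 of the 219 tested were above 0 (median 0.324). The share of the astrocyte level needed ran from 7.52% for Slc1a2, the gene of the sorted protein, to 60.4% for S100b (median 13.4%), so astrocytes low in GLT1 stay open, as do a loss of cells of several other types at once and an effect of genotype on the astrocytes themselves.

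Interferon-stimulated genes rose in all 3 R6/2 fractions at 12 weeks (medians 1.31, 2.27 and 0.51 in astrocytes, microglia and the negative fraction). In the negative fraction, though, 10 of 18 were called, and against the other genes the list did not pass with an estimated correlation (camera adjusted p = 0.426). Against microglial RNA in the astrocyte fraction, the bound written before the values were seen was not met, since the highest share that a homeostatic gene allows was 69.9% (Mertk, which astrocytes also express) and the median share needed 23.5%. A criterion set afterwards was met: the median share that 15 bright homeostatic genes allow was 0.395%, below the lowest share that any of 17 interferon genes needs (3.25%), with 12 of the 15 below that level. WT samples of a single sex are argued against, since the list kept at least 94.4% of its mean shift in each fraction without the 2 WT samples that lack Y-linked expression, and so is a linked locus acting in cis alone, since the called members, all 20 measured, lie on 11 chromosomes. A linked regulator acting in trans stays open, a response of the cells to the R6/2 genotype may remain as a hypothesis found and tested on the same data, and differences between litters in health or housing were not tested.

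Abhd1 rose in zQ175 astrocytes (2.23 and 2.22 at 6 and 12 months), microglia (1.44 and 1.18) and, called at 12 months alone, the negative fraction (1.33 and 1.22). A response to mutant huntingtin shared by both models is argued against, since the highest ratio of the R6/2 to the zQ175 fold change was -0.343, and in R6/2 at 12 weeks Abhd1 had -1.29 ± 0.31 in astrocytes (adjusted p = 0.00379), -0.49 in microglia and -0.42 in the negative fraction (adjusted p = 0.202 and 0.129). For a donor-strain segment around the knock-in allele, genes called in zQ175 astrocytes at 12 months were 0.676 times as frequent among the 100 measured genes nearest to Htt in the assembly GRCm38.p6 (4 of 100) as elsewhere (727 of 12280), below the bound of 1.5 written before. The bound was written for astrocytes alone. In zQ175 at 12 months the same ratio was 0.634 in microglia (2 of 100) and 1.595 in the negative fraction (11 of 100), the latter above 1.5. The bound was ill chosen, because a single variant gene is enough and Abhd1 is itself the 83rd nearest. A donor-strain variant at Abhd1 and an effect of the zQ175 allele cannot be told apart here, because the WT controls lack both.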

How the results depend on the processing

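The model contrasts, the leave-one-out runs of the WT counts and correlations, the fits with marker means as covariates and those without the 2 WT samples that lack Y-linked expression were chosen only after the result was seen. Counts are compared with the reported count at a ratio of 1.5, and the cause of a change was not tested. Quantile normalization within the fit kept all 27 counts and correlations, and moved the share of higher calls by less than 10 points in each count. The deposited values were already quantile normalized and nearly equal in their quantiles, so this setting could change little and is a weak check. With arrayWeights the R6/2 counts were 553, 110 and 689 at 6 weeks in astrocytes, microglia and the negative fraction, and 541, 50 and 2431 for the difference between ages. For zQ175 they were 92, 20 and 13 at 6 months, 1657 and 1241 at 12 months in astrocytes and microglia, and 5 and 1002 for the difference between ages in microglia and the negative fraction, and the model contrasts gave 2236, 432 and 2472. With only the 2 groups compared, the counts were 357 in zQ175 astrocytes at 12 months, 359 in R6/2 microglia at 12 weeks, 0 and 108 in zQ175 microglia at 6 and 12 months (limma, beside 471 and 1834 genes at an unadjusted p below 0.05 in the reported fit), 208 and 2154 in the R6/2 negative fraction at 6 and 12 weeks, and 1 and 207 in the zQ175 negative fraction at 6 and 12 months. With the Y-linked covariate they were 89 for the R6/2 difference between ages in astrocytes, 461 and 19 for R6/2 at 12 weeks and between ages in microglia, and 854 for the model contrast of the negative fraction. Without the 2 WT samples that lack Y-linked expression they were 20 for the R6/2 difference between ages in astrocytes and 475 in R6/2 microglia at 12 weeks. The dim filter at the 60th percentile gave 29 in zQ175 astrocytes at 6 months and 336 and 0 for the R6/2 and zQ175 differences between ages in the negative fraction (limma, beside 2716 genes at an unadjusted p below 0.05 for the latter in the reported fit). No dim filter gave 3 and 11 for the zQ175 difference between ages in astrocytes and the negative fraction. The mean of the probe sets gave 2 in the zQ175 negative fraction at 6 months. With markers as a covariate, limma called 0 genes in zQ175 microglia at 12 months (oligodendrocyte, endothelial and mural markers) and 122 in the R6/2 negative fraction at 12 weeks (astrocyte markers). Over all genes tested in both models the correlation in astrocytes was 0.361 (exact permutation p = 0.0143, the smallest possible).

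Leaving out each sample in turn, the lowest and highest counts at 6 and 12 weeks and for the difference between ages in R6/2 were 86 and 155, 2888 and 3493, and 53 and 192 in astrocytes, 42 and 61, 507 and 778, and 21 and 50 in microglia, and 22 and 41, 2691 and 3702, and 385 and 900 in the negative fraction. For zQ175 at 6 and 12 months and between ages they were 25 and 45, 335 and 895, and 1 and 2 in astrocytes, 1 and 2, 155 and 450, and 0 and 1 in microglia, and 0 and 0, 168 and 1560, and 1 and 34 in the negative fraction. Counts of 0 are limma's, beside 841 genes at an unadjusted p below 0.05 for the zQ175 difference between ages in microglia and 349 in the zQ175 negative fraction at 6 months with all samples. The model contrasts gave 765 and 1560, 122 and 271, and 635 and 2445, the WT comparisons 10601 and 10718, 9294 and 9436, and 10359 and 10453, and the correlations 0.425 and 0.541, 0.474 and 0.575, and 0.382 and 0.557.

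Of 957 values of named genes, each recomputed under its alternatives, 13 that were called in the reported fit or in the alternative changed direction. With the mean of the probe sets Slc6a11 in R6/2 astrocytes at 12 weeks was at 0.088 and Rarres2 in WT astrocytes against the negative fraction at 0.013. With astrocyte markers as a covariate, in the R6/2 negative fraction at 12 weeks, the values were -0.065 for Timp2, -0.18 for Apoe, -0.15 for Ctsb, -0.030 for Slc6a11, 0.22 for Stmn2, 0.083 for Birc5, 0.36 for Top2a, 0.40 for Bub1, 0.19 for Ier2, -0.037 for Sdha and 0.24 for Tbx15. Values called in neither fit changed sign in 23 leave-one-out runs, 5 with the mean of the probe sets and 3 with arrayWeights. So did 1 without the 2 WT samples that lack Y-linked expression. A call was lost in 1073 of 8222 leave-one-out values, 36 of 627 with arrayWeights, 104 of 402 with only the 2 groups, 83 of 627 with the Y-linked covariate and 64 of 857 with the mean of the probe sets. Of 69 shifts of lists by fry, 53 kept their call with the Y-linked covariate and 61 with the mean of the probe sets. In camera with an estimated correlation, which compares a list with the other genes, 14 passed.

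No paired analysis was possible for the genotype comparisons because mutant and WT samples share no replicate number. In the WT comparisons, which share them, the replicate block gave 10764, 9563 and 10530 genes, each within 1.5 times the count without it. Deviations of same-numbered WT samples correlated with median r of 0.172 for astrocytes and microglia, 0.210 for astrocytes and negative and 0.137 for microglia and negative, above 0.1 in 15, 13 and 11 of 18 numbers, and were highest for the own number in 13, 14 and 13. With not every number above 0.1 and no statement in the labels, the numbers are not established as pairing the samples. Still, WT samples 12 and 20 lacked Y-linked expression in every fraction, and WT sample 3 had low Xist in every fraction. This is a hint from the data that some numbers mark 1 pool. A change seen in several fractions may thus not count as independent observations. Signal over background limits dim genes, since those below the 40th percentile were not tested in the reported fits.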

Other observations

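No test in this part was chosen after a result was seen, since it gives values alone. WT samples 12 and 20 at 12 weeks lacked Y-linked expression in every fraction, with means of 2.91 and 2.80 in astrocytes, 3.17 and 3.85 in microglia and 3.30 and 3.12 in the negative fraction, against 8.40, 8.27 and 8.23 in WT sample 16. Xist was at 4.84, 5.46 and 5.71 in the 3 fractions of WT sample 3 at 6 weeks, against 11.93, 10.82 and 11.54 in WT sample 16 at 12 weeks. Low Xist was not a trait of that sample alone: in the 48 arrays of samples 22 to 37, at 6 and 12 months, Xist ran from 3.30 to 6.80. The microglia array of WT sample 16 had the highest mean over all probe sets, 6.82.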
